A study of Mus musculus with 2 samples.

How the data were processed

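H3K36me3 ChIP-seq was carried out on E14TG2a.4 mouse embryonic stem cells, in 2 biological replicates from separate biosamples per the labels, which also give an embryonic stage and an age of 3.5 days. Per the file lists deposited with the samples, the series holds 8 narrow peak sets on mm10 and 1 archived broad peak set on mm9. The mm10 sets come from 2 processing runs with different alignments. The main run gave, for each replicate and for both pooled, peaks supported by pseudoreplicates (random divisions of the reads of a library), and a set of peaks found in both replicates. The other run gave unthresholded peak sets for each replicate and for both pooled, and another set of peaks found in both replicates, derived from them. Each set of peaks found in both replicates covers more bases than either replicate's own set of its run, so it is not their overlap. The aligner, the peak caller, the read length and the number of reads are not given in the sources used here, and the control libraries were not used here.

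Each deposited mm10 peak has a fold enrichment (column 7, a ratio over background as the caller gave it), and a p-value and a q-value written as −log10. Tested on the files, the fold lies above 1 and −log10 p above 2 in every mm10 peak, in the unthresholded sets too, so each set was cut at some level by the authors. In the deposited mm9 set, p-values and q-values are on a linear scale. The fold is the authors' own value per peak and was used only to describe or rank within a set. Peaks were called by the authors separately for each replicate in the sets used for replicate comparisons, so differences in called coverage between replicates can come from sequencing depth, which is unknown, as well as from the cells. A narrow caller splits a broad mark into many peaks; covered bases and joined domains were therefore used beside peak numbers. The cells are of another mouse strain than the reference, C57BL/6J, so regions that differ between the strains may be under-covered.

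Gene models came from GENCODE M21 on GRCm38, the assembly that mm10 names; chromosome lengths matched and 0 peaks lay past a chromosome end. Chromosomes 1 to 19, X and Y were used. For a coding symbol with several records the longest was kept, which left out 27 records and kept 21911 genes, of which 17191 overlap no other coding gene. The gene body was the whole annotated span, and exons were merged over transcripts into blocks. The covered share is the share of bases of the gene body in peaks. Marked genes had at least 10% in each replicate. Position along the gene used marked genes of at least 3 kb, and exons were set against introns by pooling bases over marked genes with 2 or more exon blocks. Domains joined peaks within 3 kb. The uniqueness of a gene is the percent of 32-base words sampled from its body that occur once in the genome on either strand; the word length is a choice made here, as the read length is unknown.

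The replicates formed 1 group, and no conditions were compared. Overlap was counted from 1 bp, and its chance level came from 100 seeded random placements of 1 set within its chromosomes. The same number of placements tested the share of covered bases in genes. Fisher's exact test, two-sided, compared marked genes between each of 32 gene lists and all other coding genes, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05, and compared X with autosomes and genes of 1 exon block with others; odds ratios were computed with 0.5 added to each cell. The lists, 24 by symbol and 8 by symbol pattern, the thresholds and the alternatives were fixed before the data were examined, except where the text says otherwise. Coding symbols of a list absent from the annotation were left out. Each list was also placed among 10000 random lists matched on gene length in 50 bins. Genes named in the text were, for each list, up to 4 with the highest and up to 2 with the lowest covered share (the lower of the replicates), with ties in alphabetical order; the 10 genes of at least 3 kb with the highest fold over the body, again by the lower of the replicates; the 5 marked genes with the largest difference between replicates; and the 5 longest domains. Not every gene this rule selects is reported here. Others were named after their values were seen.

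Alternatives were the unthresholded sets, peaks with −log10 q of at least 5, 1 replicate left out, the other combined sets, thresholds of 5, 25 and 50% of the gene body, genes overlapping no other coding gene, long genes, other overlap rules and other gaps. Because the unthresholded sets come from the other alignments, that alternative changes both. The procedures were tested on simulated data before use. Of 200 genes given a peak over their 3′ end, among 21911 genes, 100% were recovered as marked. Of the other genes, 0.152% were called. The simulated difference between the ends of the gene was returned as 90.0 points. The ratio of exons to introns for randomly placed peaks was 1.03. Because the simulated peaks were placed by design, these values test the procedures only. They are not rates of detection or of false calls for the deposited peaks. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.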

Results

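Trimethylation of lysine 36 of histone H3 (H3K36me3), a chromatin mark known to be laid down over transcribed gene bodies, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in E14TG2a.4, a male mouse embryonic stem cell line. The labels describe 1 group of 2 biological replicates with no treatment. The comparisons the design allows are therefore those between the replicates, between parts of the genome, and between groups of genes. The files hold called peaks with their enrichment but no read counts, so the sequencing depth of either replicate is unknown. Positions are given on the mouse genome build mm10, and gene spans come from the GENCODE M21 annotation of that build. A protein-coding gene was called marked when at least 10% of its body lay in peaks in each of the 2 replicates, and covered shares are given as the mean ± SD over the 2 replicates.

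The replicates carried the mark over largely the same bases and the same genes. Replicate 1 had 107779 peaks covering 139 Mb, or 5.10% of the assembled chromosomes, and replicate 2 had 98185 peaks covering 127.0 Mb, or 4.66%. The median peak was 731 bp wide in replicate 1 and 724 bp wide in replicate 2. Of the peaks of replicate 1, 75.0% overlapped a peak of replicate 2 by at least 1 bp, and 85.7% of the peaks of replicate 2 overlapped one of replicate 1. When the peaks were placed at random within their chromosomes 100 times, the mean overlap was 7.57% and the highest was 7.73%. The bases covered in both replicates made up 73.2% of those covered in either. The covered share of each gene body correlated between the replicates with a Pearson r of 0.987 and a Spearman rho of 0.974 across 21911 protein-coding genes, which are not independent replicates. Among them, 10978 genes, or 50.1%, had no covered base in either replicate and count as agreement in both coefficients. The 26927 peaks found in replicate 1 alone were narrow, with a median of 425 bp against 937 bp for the shared peaks, and held 9.30% of its covered bases. The 14004 peaks found in replicate 2 alone had a median of 391 bp against 833 bp and held 4.84%. Where an overlap had to span 50% of both peaks, the mean of the directions dropped from 80.4% ± 7.58 (SD of the 2 directions) to 55.1%.

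H3K36me3 lay almost wholly inside protein-coding genes. These genes held 93.8% ± 0.10 (SD, n = 2) of the covered bases, whereas their spans make up 38.2% of the genome. None of 100 random placements of the peaks reached that share in either replicate; the placed mean was 40.8% in both, and the p of 0.0099 is the smallest that 100 placements can give. Introns held 72.2% ± 0.954 of the covered bases and 34.6% of the genome, while exons and untranslated regions held 21.5% ± 1.05 of the covered bases and 3.52% of the genome. The 5 kb downstream of coding genes held 3.53% ± 0.129 and the 5 kb upstream held 0.159% ± 0.0234, although these flanks take up similar shares of the genome, 2.54% and 2.29%. Other annotated genes held 1.36% ± 0.0311. The rest of the genome, 50.4% of its length, held 1.18% ± 0.0831 of the covered bases.

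Within marked genes the mark rose from the start of the gene towards its 3′ end. In 7789 marked genes of at least 3 kb, cut into 3 equal parts, the 5′ part was covered to 32.7% ± 2.41, the middle part to 59.4% ± 2.12 and the 3′ part to 68.8% ± 1.24 (SD, n = 2). The 3′ part exceeded the 5′ part by 36.1 ± 1.18 percentage points, many times the spread between replicates, and it was the more covered of the pair in both replicates in 6618 genes, or 85.0%. Of 10 equal parts, the one at the 5′ end was covered to 12.5% ± 1.58, and coverage was highest in part 9, at 70.8% ± 1.04, before 68.1% ± 1.16 in part 10. The window of 500 bp on either side of the transcription start was covered to 1.79% ± 0.0637, and that around the gene end to 57.3% ± 1.73. Coverage ran on past the gene end: among 1617 marked genes whose 5 kb flanks overlapped no other gene, the downstream flank was covered to 19.6% in replicate 1 and 16.8% in replicate 2, and the upstream flank to 1.36% and 1.09%. Among 5882 unmarked genes with such flanks, the downstream flank was covered to 0.544% and 0.460%. In marked genes of at least 30 kb the gain from the 5′ to the 3′ part was 27.2 points.

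**Figure D1:**
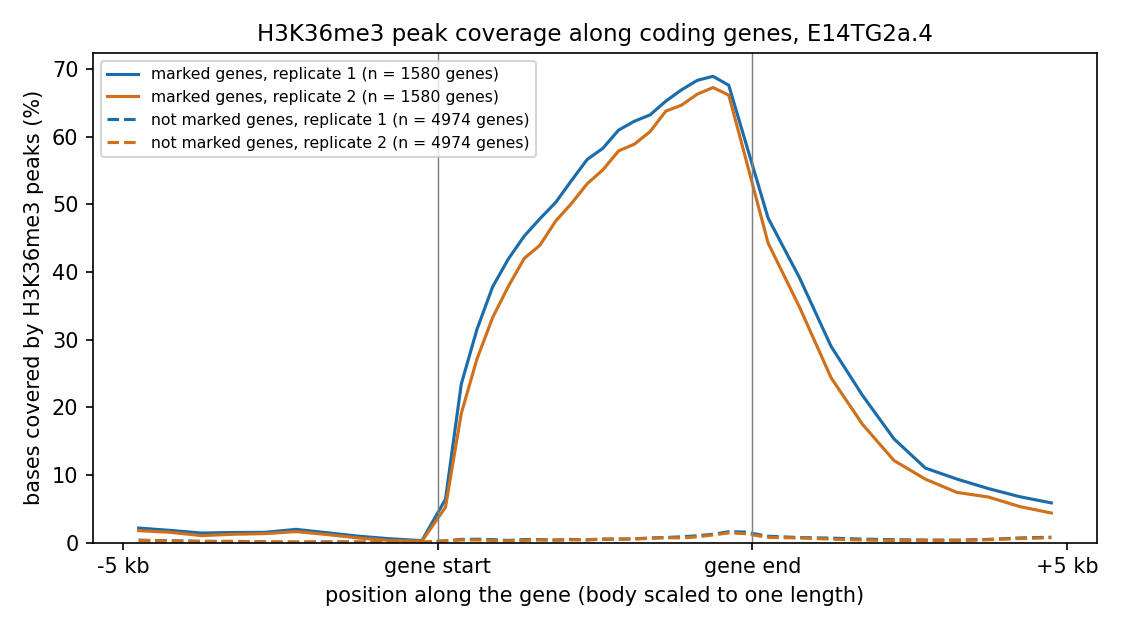
Share of bases covered by H3K36me3 peaks (vertical axis, %) along protein-coding genes of at least 3 kb with clear flanks, from 5 kb upstream through the scaled gene body to 5 kb downstream (horizontal axis). Solid lines are 1580 marked genes and dashed lines 4974 unmarked genes, with 1 line per replicate; both replicates show low coverage at the gene start and the highest coverage just before the gene end.

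Exons were covered more fully than introns of the same genes. In 8010 marked genes with 2 or more exon blocks, 64.1% ± 0.960 of exonic bases and 41.6% ± 2.97 of intronic bases were covered, a ratio of 1.55 ± 0.0872 (SD, n = 2). Within the 3′ part of the gene alone, where coverage is higher throughout, the shares were 70.8% ± 0.984 and 55.1% ± 2.41 and the ratio was 1.29 ± 0.0384. Weighting each gene equally, so that long genes did not dominate, gave 1.26. The ratio thus remained above 1 but was smaller within the 3′ part and with equal weight per gene. Equal weight was not applied within the 3′ part, so position and gene length were not accounted for together.

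The marked set comprised 8155 of 21911 protein-coding genes, or 37.2%, with a median of 57.1% of their bodies covered in replicate 1 and 52.9% in replicate 2. Another 372 genes passed in replicate 1 alone and 180 in replicate 2 alone. In contrast, 10978 genes, or 50.1%, had no covered base in either replicate. The 10 genes with the highest fold enrichment over the gene body (the authors' fold per peak, averaged over all bases of the gene, and ranked by the lower of the 2 replicates) were Eif3f, Lig1, Prmt5, Slc2a1, Prpf8, Eef2, Noc2l, Cherp, Gpi1 and Mybbp1a. Eif3f (chromosome 7, 108934417 to 108942951), a subunit of a translation initiation factor, had a fold of 16.6 in replicate 1 and 18.3 in replicate 2. Lig1 (chromosome 7, 13277283 to 13311433), the DNA ligase of replication, reached 16.4 and 20.6, and Prmt5 (chromosome 14, 54507187 to 54517525), an arginine methyltransferase, reached 16.02 and 24.2. Slc2a1, the glucose transporter GLUT1, was covered to 96.5% ± 0.763, Prpf8, a core spliceosome protein, to 96.4% ± 0.469, and Eef2, the elongation factor of translation, to 94.4% ± 0.964. The highest single peak in each replicate lay in Zfp532, a zinc finger gene on chromosome 18: it ran from 65623267 to 65630068 with a fold of 21.2 in replicate 1 and from 65623274 to 65630031 with a fold of 37.4 in replicate 2.

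Replicates differed in single genes by a median of 3.68 percentage points of the gene body over the marked genes, and 95% of them differed by at most 14.7 points. The differences leaned to 1 side, with replicate 1 higher in 5608 of the 8155 genes and replicate 2 in 2507. The 5 largest differences were all in genes under 5 kb. Egfl8 was covered to 97.6% in replicate 1 and 50.4% in replicate 2, Spaca4 to 100% and 55.9%, Gm21885 to 80.9% and 37.5%, and C1qtnf5 to 82.9% and 39.7% (a mean of 61.3%, which fell to 40.6% at −log10 q of at least 5). Ckb, the brain form of creatine kinase, went the other way, with 38.4% in replicate 1 and 82.8% in replicate 2.

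Joining peaks within 3 kb gave 21762 domains in the set of peaks that the authors found in both replicates, and 20719 and 20889 in the replicates. That set covered 162 Mb, more than either replicate, so the share of a gene in it can exceed the share in both replicates. The 5 longest domains each lay along 1 large coding gene. The longest ran for 236 kb over Dnah8, an axonemal dynein heavy chain gene, on chromosome 17 (30628751 to 30865151), with 78.0% ± 5.39 of it in peaks. It was followed by 187 kb over Tns3 (chromosome 11, 8429070 to 8616347), 167 kb over Enox1 (chromosome 14, 77556595 to 77723443), 161 kb over Vps13d (chromosome 4, 145031306 to 145191863) and 157 kb over Dst (chromosome 1, 34152191 to 34309327). Their covered shares were 89.1% ± 3.12, 86.8% ± 3.88, 64.3% ± 2.66 and 81.4% ± 0.713 in that order. The number of domains depends on the gap allowed, with 37593 at 1 kb and 11470 at 10 kb.

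Genes of the pluripotent state were marked far more often than other genes. Of 20 general pluripotency genes 18 were marked, and of 18 genes of the naive state 17 were marked, against 37.2% of other coding genes (Fisher's exact test, two-sided, adjusted over 32 lists by Benjamini-Hochberg; adjusted p = 3.0e-06 and 1.3e-06). The most fully covered general members were Rif1, a telomere and replication timing factor, at 91.0% ± 0.233, Fbxo15 at 83.9% ± 1.69, Zfp42, also known as Rex1, at 80.1% ± 2.15 and Tdgf1, the Nodal co-receptor Cripto, at 73.1% ± 1.83. The core transcription factors, named here outside the rule for naming genes, were covered to 66.8% ± 2.80 for Pou5f1 (Oct4), 72.5% ± 12.7 for Sox2 and 66.7% ± 6.85 for Nanog. Among naive genes Klf5 stood at 89.5% ± 0.813, Tfcp2l1 at 82.0% ± 4.16 and Il6st, the gp130 receptor chain through which LIF signals, at 79.2% ± 2.05. The unmarked members were Dppa5a and Lin28b in the general list and Dppa3, also called Stella, in the naive list. No base of Dppa5a or Dppa3 was covered in either replicate; 16% of the 32-base words of Dppa5a and 81.5% of those of Dppa3 occur only once in the genome. Genes of the primed state gave no call, with 6 of 14 marked (adjusted p = 0.783, exact test): Dnmt3b was covered to 82.4% ± 4.81, Nodal to 77.6% ± 1.31 and Zic2 to 43.7% ± 0.752, while Fgf5 and Cer1 had no covered base.

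Genes of the chromatin machinery were marked often as well. Among writers, erasers and readers of H3K36 methylation, 20 of 23 were marked (adjusted p = 2.6e-06, exact test), led by Msh6, a mismatch repair protein that binds H3K36me3, at 92.5% ± 1.12, the demethylase gene Kdm4a at 88.1% ± 0.671, Psip1, which encodes the reader LEDGF, at 87.5% ± 0.839 and Brpf1 at 85.9% ± 0.263. Kdm4d had no covered base. Phf19 was covered to 2.62% ± 0.816, with 3.20% in replicate 1 and 2.04% in replicate 2. Its share was 12.2% in the unthresholded sets and 15% in the set of peaks found in both replicates. The latter set covers more bases than the set of either replicate. Of 16 DNA methylation genes 13 were marked (adjusted p = 6.9e-04, exact test), with Uhrf1, which brings the maintenance methyltransferase to replicated DNA, at 92.6% ± 0.323, Tet1 at 79.9% ± 0.531 and Dnmt1 at 77.4% ± 0.885; Tet3 was covered to 1.75% ± 0.648, to 0.663% at −log10 q of at least 5, to 5.14% in the unthresholded sets and to 6.69% in the set of peaks found in both replicates. Of 26 Polycomb genes 21 were marked (adjusted p = 2.2e-05, exact test), with Eed at 88.8% ± 1.79 and Suz12 at 85.7% ± 3.55, both core subunits of PRC2, whereas Bmi1 of PRC1 had no covered base.

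Genes that dividing cells use throughout were marked nearly without exception. All 24 splicing factors, all 26 genes of mitochondrial electron transport and all 18 genes of the chaperonin and translation list were marked, as were 24 of 25 proteasome genes, 81 of 84 ribosomal protein genes, 15 of 16 glycolysis genes and 27 of 29 genes of the cell cycle and DNA replication (adjusted exact p = 2.0e-10, 3.1e-11, 4.9e-08, 2.3e-09, 3.4e-30, 7.1e-06 and 1.3e-09, in that order). Mcm5, a subunit of the replicative helicase, was covered to 97.5% ± 0.206, Gpi1, the glycolytic enzyme glucose-6-phosphate isomerase, to 97.1% ± 0.178, Sf3a1 to 96.1% ± 0.793, Cct3 to 94.6% ± 0.594, Rpl23 to 93.2% ± 0.835, Atp5b to 90.4% ± 1.00 and Psmd2 to 89.4% ± 0.301. Unmarked members of these lists included Hk1 at 6.75% ± 0.0331 (11.6%, above the threshold of 10%, in the set of peaks found in both replicates). Ccnd3 was covered to 4.19% ± 0.383 (7.08% in the unthresholded sets). Rpl10l and Rpl3l, taken into the ribosomal protein list by symbol pattern, had no covered base. Of 14 genes of the p53 pathway 10 were marked (adjusted p = 0.0146, exact test), among them Trp53 itself at 83.6% ± 5.11 and Mdm2 at 85.9% ± 0.449; Fas and Perp had no covered base, although Perp was covered to 2.38% in the unthresholded sets. Genes with Zfp symbols, most of which encode zinc finger proteins, were marked in 234 of 391 cases (odds ratio 2.56, adjusted p = 5.4e-19, exact test), with Zfp202 covered to 92.9% ± 0.648 and Zfp335 to 90.2% ± 1.12.

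Genes of other lineages were mostly unmarked. None of 39 Hox genes, 16 blood and immune genes, 15 liver genes or 13 genes of the 2-cell-like state was marked (adjusted exact p = 6.1e-08, 0.00159, 0.00280 and 0.00435). The mesoderm and cardiac list had 1 marked gene of 18, Tbx6, at 70.5% ± 11.7 (adjusted p = 0.00752), and the germ line list 1 of 16, the synaptonemal complex gene Sycp3, at 20.6% ± 8.09, or 31.8% in the set of peaks found in both replicates (adjusted p = 0.0113, both exact tests). Sycp3 overlaps another coding gene, so its coverage cannot be assigned to it alone. Without such genes the germ line odds ratio was 0.0656 (adjusted p = 0.00605, exact test). Of 15 trophoblast genes only Tfap2c was marked, at 59.3% ± 9.45 (adjusted p = 0.0173, exact test). The trophoblast call did not hold in the same exact test with a threshold of 25% of the gene body (adjusted p = 0.0600), with replicate 2 alone (adjusted p = 0.0726) or among genes that overlap no other coding gene (adjusted p = 0.0540). No call was made for primitive endoderm, with 3 of 16 marked (adjusted p = 0.207, exact test), neural genes, with 3 of 20 (adjusted p = 0.0722), or fibroblast genes, which would mark feeder cells, with 3 of 18 (adjusted p = 0.10). The primitive endoderm genes were the laminin chains Lamb1 at 80.2% ± 1.81, Lama1 at 50.2% ± 0.487 and Lamc1 at 38.0% ± 4.13. The neural genes were Gad1 at 45.2% ± 5.49, Tubb3 at 34.8% ± 0.507 and Pax6 at 19.4% ± 3.62. The fibroblast genes were Fn1, which encodes fibronectin, at 95.4% ± 0.624, Vim at 65.3% ± 3.00 and Sparc at 52.2% ± 5.92; the fibrillar collagen genes Col1a1 and Col1a2 had no covered base. In the same exact test, the neural list passed with replicate 2 alone (adjusted p = 0.0479) and the fibroblast list in the set of peaks found in both replicates (adjusted p = 0.0398).

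The olfactory and vomeronasal receptor, keratin, defensin and replication-dependent histone families were almost unmarked. Of 1134 olfactory receptor genes 1 was marked, Olfr986, whose span ends 2.18 kb from that of the marked gene Zfp202, and none of 326 vomeronasal receptor, 49 keratin, 64 defensin or 67 replication-dependent histone genes was (adjusted exact p = 2.2e-233, 5.6e-66, 5.3e-10, 1.0e-12 and 2.2e-13). Hist3h2a came nearest among the histones, with 29.4% in replicate 1, 9.18% in replicate 2 and 31.5% in the set of peaks found in both replicates; a median of 43.5% of the 32-base words of a histone gene occur only once in the genome, against 94.0% over all coding genes. Of 56 protocadherin genes of the clusters 16 were marked, all in the gamma cluster on chromosome 18, whose annotated genes overlap and share a 3′ part (adjusted p = 0.220, exact test), with Pcdhgc5 at 40.7% ± 2.12 and Pcdhgc4 at 40.6% ± 1.84. At a threshold of 25% of the gene body this list fell below other genes (odds ratio 0.153, adjusted p = 2.1e-05, exact test). Genes are not independent replicates, so these p-values describe the present libraries. Medians of the lists above other genes lay at or beyond the 98.5 percentile of 10000 random lists matched on gene length. For the lists below, except the germ line list, medians of both the list and the random lists were 0, so the percentile carries no information there. The germ line list had a median of 0 against 4.89% for the random lists. It lay at percentile 11.3, so matching on length did not set it clearly apart.

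**Figure D2:**
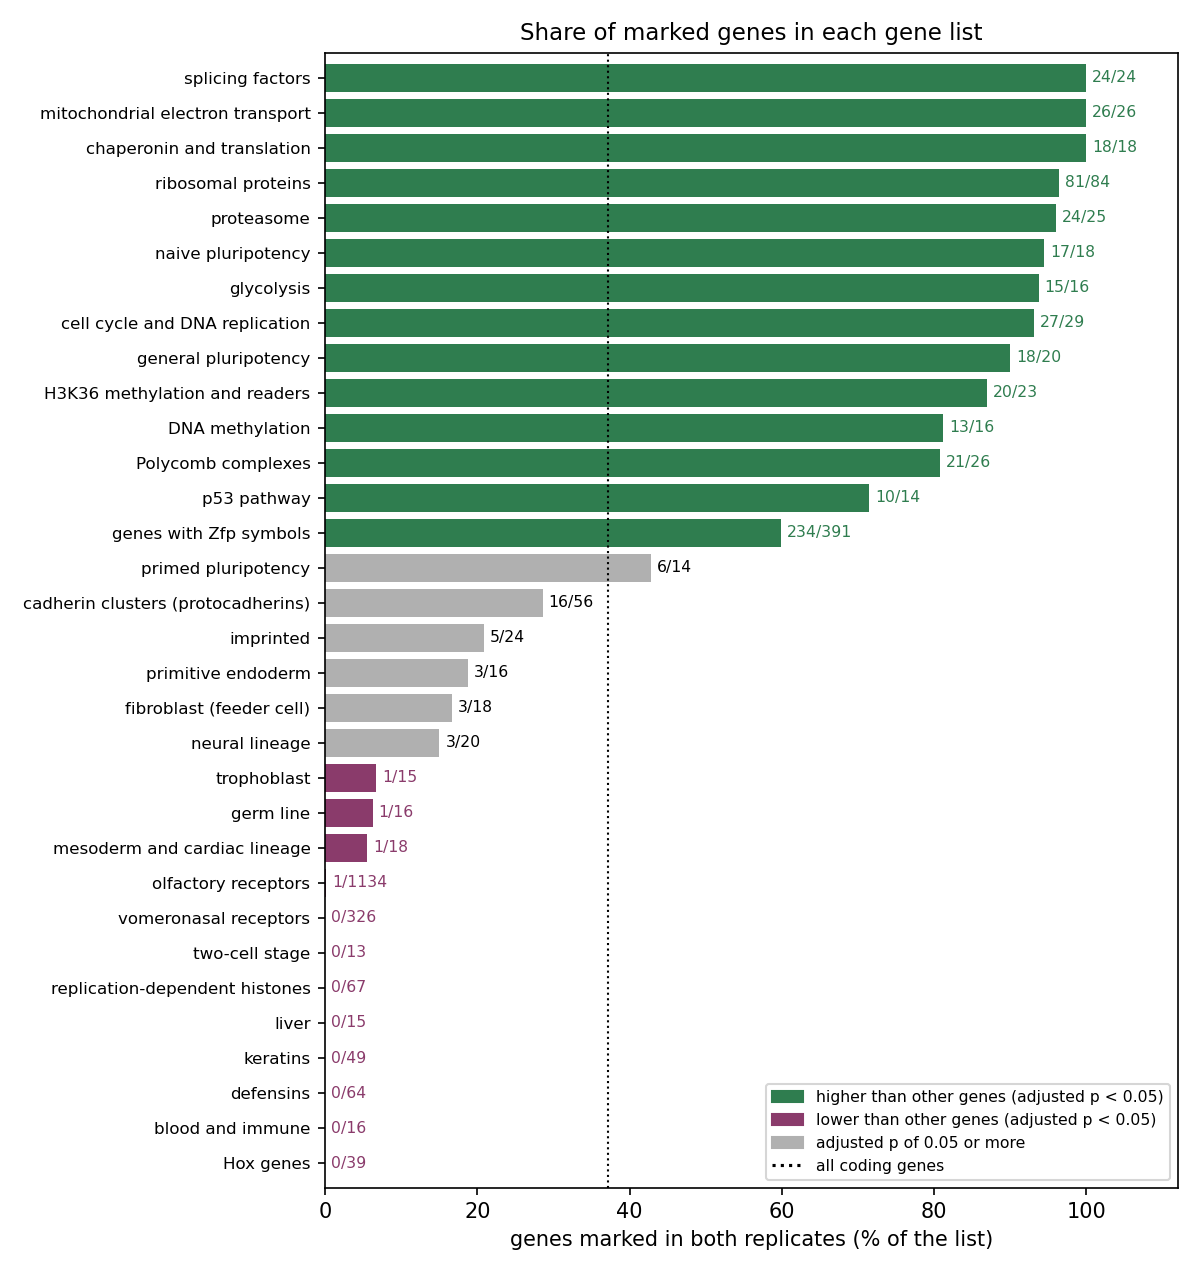
Share of genes marked in both replicates (horizontal axis, % of the list) for 32 gene lists, with marked genes over all genes of the list beside each bar. Green bars and counts are lists above other coding genes, purple ones are lists below, grey bars did not pass the test, and the dotted line is the share among all coding genes, 37.2%; 14 lists lie above, 12 below and 6 show no call.

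Imprinted genes, which are expressed from the copy inherited from a given parent, gave no call as a list, with 5 of 24 coding members marked, or 20.8% (odds ratio 0.475, adjusted p = 0.152, exact test). Igf2r was covered to 57.5% ± 0.323, Nnat to 48.1% ± 14.2, Peg3 to 47.1% ± 5.71 and Impact to 34.5% ± 1.94, whereas Dlk1 and Cdkn1c had no covered base (0.774% for Cdkn1c in the unthresholded sets). The non-coding members differed from each other: Meg3 was covered to 85.2% ± 1.66, H19 had no covered base, and Peg13 was covered to 2.83% ± 4.00. Meg3 opens a domain of 157 kb on chromosome 12 (109544524 to 109701059) that takes in Rtl1, at 89.9% ± 3.07, and the non-coding gene Rian, at 66.1% ± 3.51; a further stretch covers Mirg to 92.6% ± 0.700. Rtl1 lies on the opposite strand to Meg3, Rian and Mirg. Peaks were used without strand, so its coverage cannot be assigned to Rtl1 itself. This region was chosen for display after its values were seen.

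**Figure D3:**
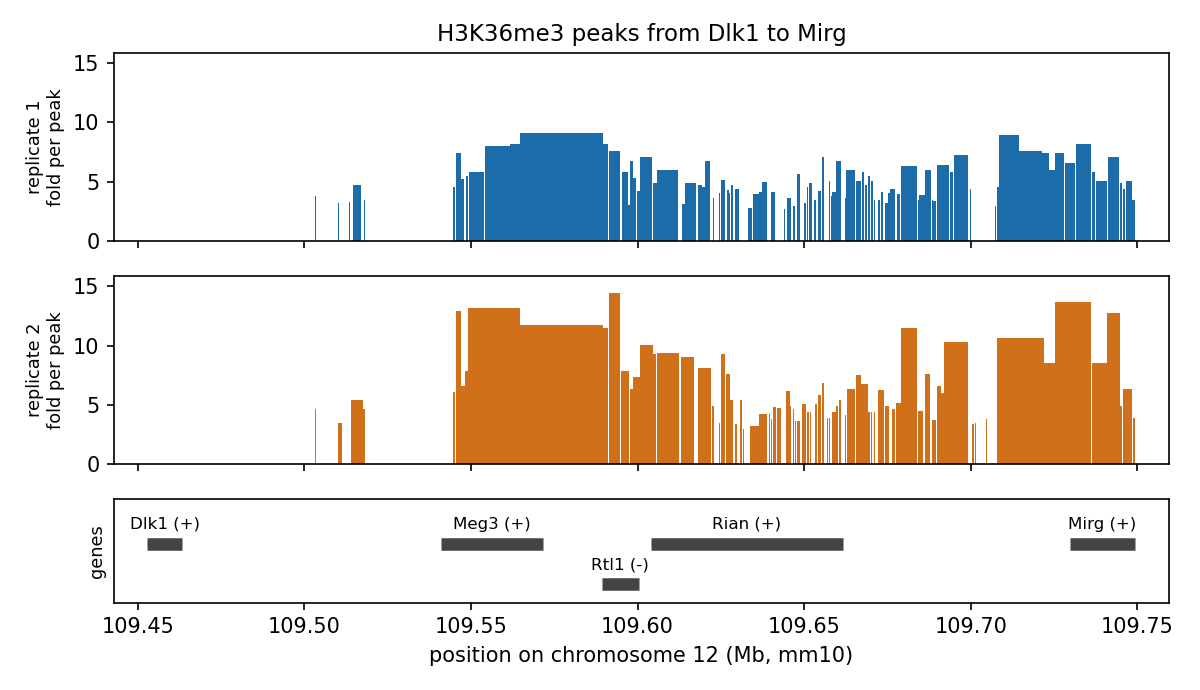
H3K36me3 peaks of replicate 1 (upper track) and replicate 2 (middle track) from Dlk1 to Mirg on chromosome 12 (horizontal axis, Mb on mm10), drawn to scale with the authors' fold per peak as height, above the spans and strands of 5 genes. Peaks fill most of the stretch from Meg3 to Mirg in both replicates, and Dlk1 holds none.

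Long non-coding RNA genes and pseudogenes that overlap no coding gene were rarely marked. Of 6031 such long non-coding RNA genes 175 were marked, or 2.90%, and of 11014 such pseudogenes 82, or 0.745%; no test was run on these shares. Among coding genes, those with 1 exon block were marked less often than those with more, in 145 of 1458 against 8010 of 20453 (9.95% against 39.2%, odds ratio 0.172, p = 1.0e-131, Fisher's exact test, two-sided). Among genes of 1 to 10 kb the shares were 14.5% and 32.9%, with an odds ratio of 0.346 (p = 9.7e-32, the same exact test). The almost unmarked gene families above were not left out of these comparisons, so exon number was not separated from gene family. By gene length, the marked share was 3.78% under 1 kb, 20.4% from 1 to 3 kb, 33.8% from 3 to 10 kb, 48.1% from 10 to 30 kb, 46.3% from 30 to 100 kb and 18.4% above 100 kb.

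The line is male and has 1 X chromosome, which bears on how X-linked genes compare with autosomal ones. On X, 180 of 948 coding genes were marked, or 18.99%, against 7974 of 20780 on autosomes, or 38.4% (odds ratio 0.377, p = 1.6e-36, Fisher's exact test, two-sided). Each replicate gave the same picture, with odds ratios of 0.383 and 0.384. Peaks covered 1.25% of X in replicate 1 and 1.17% in replicate 2, and the median fold of its peaks was 4.00 and 4.89, against 4.37 and 5.0 for autosomal peaks. Marked X genes were covered to a median of 43.0% in replicate 1 and 41.1% in replicate 2, less than the 57.4% and 53.3% of marked autosomal genes. On Y, 1 of 183 coding genes was marked, the RNA helicase gene Ddx3y, at 14.9% ± 6.52. Among autosomes the marked share ranged from 29.5% on chromosome 6 to 46.4% on chromosome 8.

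**Figure D4:**
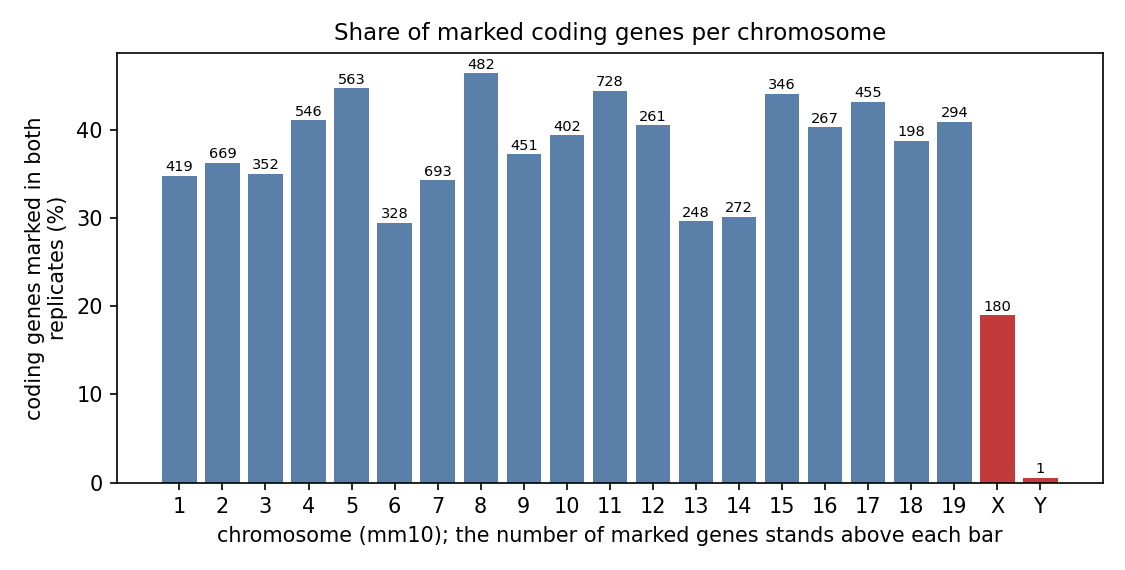
Share of coding genes marked in both replicates (vertical axis, %) on each chromosome (horizontal axis), with the number of marked genes above each bar; autosomes are blue, X and Y are red. X, at 18.99%, and Y, at 0.546%, lie below every autosome, of which the lowest is chromosome 6 at 29.5%.

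The series also holds an archived set of broad regions on the older build mm9, which was compared only through quantities that need no conversion of positions. It listed 27636 regions of 10693 bp on average that covered 296 Mb, 1.83 times the 162 Mb of the mm10 set of peaks found in both replicates. The distribution over chromosomes was close: the largest difference in share of covered bases was on chromosome 11, with 7.62% in the mm9 set and 8.47% in the mm10 set. X held 2.00% and 1.66%.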

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

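Of the tests below, the one on the pooled unthresholded set, the one on X with both filters, the one on genes under 1 kb, the one on histone genes with mostly unique sequence and the one on first exons of protocadherins were chosen after related results had been seen. The design holds 1 group, so no biological explanation was tested for any pattern.

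Peaks outside the assembled chromosomes appeared in sets that no comparison above uses on that sequence: the unthresholded set of replicate 1 had 23 peaks and that of replicate 2 had 27 peaks on unplaced or unlocalized sequences, and the sequence GL456368 held 12 and 13 of them, with a fold of up to 7.08 and 8.6. The set of peaks found in both replicates of the same run kept 20, and the peak sets of the main run had 0.

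The lower share of marked genes on X was weighed against 3 technical explanations. If 1 copy of X gave too little signal to call peaks, a more permissive set should close the gap, yet in the pooled unthresholded set 24.6% of X genes and 45.5% of autosomal genes were marked, an odds ratio of 0.391; however, that set changes pooling, threshold and alignments at once, and marked X genes were covered to a median of 43.0% and 41.1% in the 2 replicates against 57.4% and 53.3% of marked autosomal genes, which a lower signal from X would give, so this explanation stays open. Without predicted gene models and clustered families, 25.4% of 672 X genes and 46.8% of 15981 autosomal genes were marked, an odds ratio of 0.389 (p = 7.9e-29, Fisher's exact test, two-sided). Among genes with at least 90% unique words, which discounts reads shared between near-identical copies, the shares were 26.5% and 44.2%, an odds ratio of 0.456 (p = 5.1e-15, the same exact test). With both filters the shares were 28.8% of 424 X genes and 49.0% of autosomal genes, an odds ratio of 0.422 (p = 1.0e-16, the same exact test), so neither families nor shared reads account for the gap, alone or together, while the single copy is not excluded.

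That none of the 67 replication-dependent histone genes, which dividing cells express strongly, was marked in both replicates was weighed against gene length and shared reads. Of 11 housekeeping genes of at most 2 kb 9 were marked, or 81.8%, but their median length was 1.26 kb against 0.539 kb for the histone genes, so the bound set beforehand was wrong, as these genes are too long to exclude gene length. Under 1 kb, 0 of 48 histone genes and 27 of 667 other coding genes were marked, or 4.05% of the latter (p = 0.248, Fisher's exact test, two-sided). With so few genes of this length marked, even a count of 0 could not set the histone genes apart. The test therefore cannot decide on gene length, which stays open. Reads shared between near-identical copies remain a candidate explanation, as a median of 43.5% of the words of a histone gene occur once in the genome, against 94.0% over all coding genes. Of the 16 histone genes with at least 80% unique words 0 were marked, against 127 of 833 other coding genes of at most 2 kb with such uniqueness, or 15.2% (p = 0.149, Fisher's exact test, two-sided). This comparison cannot decide on shared reads. The 16 genes are too few, and the other genes, of up to 2 kb, were not matched to the histone genes on length.

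The 16 marked genes of the protocadherin gamma cluster were weighed against the way the cluster is annotated, in which each gene has its own first exon and all share a common 3′ part. Of the 16, 3 genes, or 18.8%, had at least 10% of their own first exon block covered in both replicates. This cannot decide the question, because marked genes of at least 3 kb were covered to only 12.5% ± 1.58 in the first of 10 equal parts. The first exon blocks of the 16 genes were covered to 8.54% in replicate 1 and 7.77% in replicate 2 on average. The stretch from the start of Pcdhgc5 to the end of the cluster was covered to 39.2% and 42.2%, a contrast that the general rise towards the 3′ end would also give. That stretch held 56.2% and 63.9% of the covered bases summed over the 16 gene models, so part of the coverage lies upstream of it. In this sum a base shared by several models is counted once for each. Because that stretch is counted in every model, the number of gamma genes with a mark of their own may be lower than 16.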

How the results depend on the processing

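The lists were rerun at 25% of the gene body, with each replicate left out, in the main set of peaks found in both replicates and among genes overlapping no other coding gene; the tests added in the closing section had no alternatives. Where rerun, the tested comparisons kept their direction, except for the list of primed genes, whose odds ratio of 1.29, without a call, turned to 0.712 at 25% of the gene body (adjusted p = 0.575, Fisher's exact test). The share of covered bases in genes stayed between 92.9% and 94.1% in the settings run, which leave out the pooled unthresholded set and the mm9 set, and above every random placement. For the 2 replicates it also lay above every placement with the peaks of a chromosome shifted together, a check added after seeing the data. The odds ratio of X against autosomes ranged from 0.327 to 0.385 over the planned settings (the filters and the pooled unthresholded set are in the closing section) and that of genes with 1 exon block from 0.153 to 0.346. Overlap of the replicates moved to 55.1% with 50% of both peaks required. The correlation of gene coverage was 0.987, with a 95% interval of 0.000339 on either side that counts genes as independent, which they are not, so it is too narrow; the small changes to 0.989 in the unthresholded sets, 0.986 at −log10 q of at least 5 and 0.989 for genes overlapping no other are not read as beyond chance. Marked genes numbered 4220 at 50% of the gene body against 8155, as a stricter threshold must give fewer. Other settings over all 21911 genes gave 6557 to 9254, and leaving out a replicate 8335 to 8527. Among the 17191 genes overlapping no other coding gene, a smaller set, 5659 were marked. The gain towards the 3′ end moved to 27.2 points in genes of at least 30 kb (the cause was not tested) and ranged from 34.4 to 36.6 points with a replicate left out. The ratio of exons to introns moved to 1.29 within the 3′ part and to 1.26 with equal weight per gene, the latter added after seeing the data, and was 1.55 to 1.61 with a replicate left out. Domains numbered 37593 with a gap of 1 kb and 11470 with 10 kb, as the gap itself dictates. Lists with a call numbered 25 to 27 against 26. Of 159 recomputed list values 152 kept both direction and side of the threshold; the 6 others besides the primed list were the calls on trophoblast, neural, fibroblast and protocadherin genes given in the report. For protocadherins among genes overlapping no other coding gene no value could be computed. The combined mm10 sets other than the pooled unthresholded set, which had 181884 peaks, held 109076 to 121646 peaks. The mm9 comparison differed by less than 0.1 points between mm10 sets. Of 606 recomputed values for 202 named genes, 441 stayed within 1 SD of the replicates and 580 within 10 points. No paired analysis was possible because the series holds 1 group. The unknown depth limits what the absence of a peak can show.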

Other observations

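Beyond the lists, several long non-coding RNA genes, picked after their values were seen, carried the mark over much of their length (mean ± SD, n = 2). Snhg1 and Gas5, which host small nucleolar RNAs, were covered to 88.4% ± 3.81 and 79.3% ± 1.27, Malat1 to 86.4% ± 3.58, and Firre, an X-linked gene, to 50.7% ± 1.05. Platr22, of a class named for its link to pluripotency, was covered to 55.5% ± 4.81 and Lncenc1 to 39.9% ± 0.798. Pvt1, next to Myc, reached 36.7% ± 10.5 and Neat1 21.4% ± 7.86, while Airn, antisense to the imprinted gene Igf2r, was covered to 3.59% ± 0.295.

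Of 21762 domains in the set of peaks found in both replicates, 1587, or 7.29%, touched no annotated gene, and 27 of these were longer than 10 kb. The longest ran for 57.05 kb on chromosome 5 (33477189 to 33534238), 43.2 kb from the nearest coding gene, Nkx1-1, and was covered to 79.3% in replicate 1 and 82.5% in replicate 2. Another of 33.2 kb lay on chromosome 2 (172578821 to 172612057), 20.2 kb from Tfap2c, the marked gene of the trophoblast list, with 63.7% and 67.9%. One of 18.8 kb on chromosome 8 (78069559 to 78088320) lay 125.0 kb from the nearest coding gene, Ttc29, with 60.4% and 56.2%. Whether these are transcribed was not analysed here.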
